A study of Rattus norvegicus with 8 samples.

How the data were processed

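Gene expression was measured in NR8383 cells, a rat alveolar macrophage line started from lavage of a normal rat lung, after 4 h in serum-free medium without or with 0.17 µg/mL of the multi-walled carbon nanotube NM401. Per the labels, each condition had 4 biological replicates, so 8 arrays were used, 4 control and 4 NM401. Total RNA was turned into Cy3-labelled cRNA and hybridised to 1-colour Agilent arrays, per the labels' protocols. The authors deposited scanner files with spot intensity values made by Agilent Feature Extraction 11.0.1.1, per the file headers. The processed signal in them was background-subtracted and spatially detrended within each array, per the file headers, and was not scaled between arrays. The deposited series table held, for 503808 of 503808 spot values compared, exactly the median pixel intensity of the same spot in the scanner files, so its values were linear intensities that were neither background-subtracted nor scaled or centred. Its column medians were 73, 80, 74 and 73 for control replicates 1 to 4 and 105, 100, 110 and 106 for NM401 replicates 1 to 4.

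Each array held 62976 spots, of which 58717 were not controls. These spots stood for 45598 probes, 43279 with 1 spot, 969 with 2 spots and 1350 with 10 spots. Spots marked as outliers by the software were left out, spots of a probe were averaged on the log2 scale, and 47 probes whose spots were all marked on some array were dropped. No spot was saturated (0 on the 8 arrays). The main values were log2 of the processed signal minus the 75th percentile of it over the non-control spots of the same array. Probes well above background on at least 4 of the 8 arrays were tested, which left 21684 probes. A probe's accession was named through a RefSeq gene table of the rat (assembly GRCr8, used for names only), which matched 21109 of the 45598 probes, and the files' own gene name was kept otherwise. Probe positions are those in the files, on rat build rn4 per the file headers. A gene was represented by its tested probe with the highest mean log2 signal over the 8 arrays, which gave 17444 genes, 10866 with a gene symbol and 6578 with only an accession, a locus number or a similar placeholder. Of 3315 genes with several tested probes, 188 had called probes that went in opposite directions.

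NM401 arrays were compared with control arrays with limma 3.58.1 (lmFit and eBayes, two-sided) in R 4.3.3, with no covariate and with the package data.table (version 1.17.8) for reading the files, and p-values were adjusted by Benjamini-Hochberg over all probes tested. A gene was called at an adjusted p below 0.05. Differences are log2 fold changes, NM401 minus control, with the standard error (SE) of the fit. Where a representative probe was not well above background on any array of a group, the difference is a bound, written as at least N-fold: the other group's mean against the mean of, per array, the higher of the probe's own value and the lowest value among probes well above background. Such a bound holds for the processed signal, with the background as subtracted in the deposited files. The number of arrays, 4 in each group, limits the precision.

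Before the data were examined, 24 gene lists and 5 lists of cell type markers were fixed, together with the tests of genes and lists, the rule for naming genes and all but 1 of the alternatives tried. The gene lists were chemokines, inflammatory cytokines and mediators, NF-kappaB target and feedback genes, inflammasome and pyroptosis, NRF2 oxidative stress response, metal response, unfolded protein and integrated stress response, heat shock response, p53 and DNA damage response, type I interferon response, cholesterol biosynthesis and uptake, lipid efflux and LXR targets, immediate early genes, mitosis, DNA replication, glycolysis and hypoxia, oxidative phosphorylation, cytosolic ribosomal proteins, ribosome biogenesis, proteasome, scavenger and phagocytic receptors, lysosome and autophagy, matrix remodelling and fibrosis mediators, and actin cytoskeleton and adhesion. The marker lists were for macrophages, alveolar and airway epithelium, lymphocytes, fibroblasts and endothelium, and neutrophils. The 26 lists with at least 5 measured members were tested with camera of limma on the representative probes, with a preset inter-gene correlation of 0.01, and adjusted by Benjamini-Hochberg over the 26 lists. Genes named in the text had a symbol. The 12 largest differences in each direction were taken among genes called with no overlap between the 4 control and the 4 NM401 values, and in each list up to 4 members with the smallest p. The narrowing to 4 members in lists that passed and 2 in the others was chosen after the results had been seen, to shorten the text. Further members are given by name only, some of them chosen after their values were seen. Some genes that the rule names are not reported here.

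The alternatives were normexp background correction with an offset of 50 on the mean and local background intensities, quantile normalisation, scaling by the median of each array, no filter on dim probes, a filter on all 8 arrays, the deposited series values, the replicate number as a block, slide as a block, a variance trend with robust estimation, array weights, the mean of all probes of a gene, a fold change of at least 1.5, and each replicate left out in turn. For lists, camera with an estimated correlation and fry were also run. A fit on the arrays of slide 1 alone was added after seeing the data. Slide and scan gave the same division of the arrays. The method was tested on simulated data for NM401 against control with 17444 genes, where it called 68.7% of the genes changed by 1.5-fold, 86.6% of those changed by 2-fold and 97% of those changed by 4-fold, along with 7 unchanged genes and the 1 shifted list. Only 67, 67 and 66 genes were changed by these folds, and every member of the list was shifted by 1.5-fold. Noise was independent between probes, with no slide or array-wide effect. The simulation therefore does not cover changes in a large share of genes, correlated genes or batches.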

Results

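The data describe the response of NR8383 rat alveolar macrophages to multi-walled carbon nanotubes (NM401) at 0.17 µg/mL for 4 h, with 4 control and 4 NM401 arrays of biological replicates. The comparison asks which transcripts differ between cells kept without and with the nanotubes. Between 51.7% and 58% of non-control spots were well above background on each array, with means of 54.1% ± 2.14 (SD, n = 4) in control and 55.4% ± 1.82 (SD, n = 4) in NM401 (exact permutation p = 0.429, two-sided). The 75th percentile of the signal was 1240 ± 225 (SD, n = 4) in control and 2690 ± 173 (SD, n = 4) in NM401, with no overlap between groups (exact permutation p = 0.0286, the smallest that 4 against 4 arrays allow). All 4 control arrays and NM401 replicate 1 were on slide 1, and NM401 replicates 2 to 4 were on slide 2. The control arrays lay in row 1 of a slide and the NM401 arrays in row 2, so row and group cannot be told apart. Values of single genes were correlated across genes at r = 0.989 to 0.996 between control arrays, 0.991 to 0.996 between NM401 arrays and 0.966 to 0.983 between groups, where genes are not independent replicates.

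**Figure D1:**
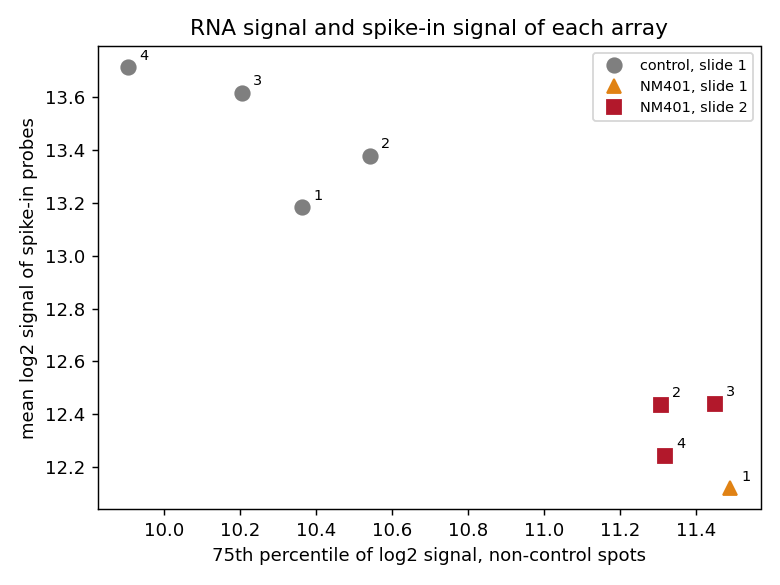
Mean log2 signal of the spike-in probes (vertical axis) against the 75th percentile of log2 signal of the non-control spots (horizontal axis) for each of the 8 arrays, with the replicate number beside each point and the slide given by colour and shape. The NM401 arrays, including the one on slide 1, lie between 11.31 and 11.49 on the horizontal axis and the control arrays between 9.90 and 10.54.

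With NM401, the monocyte chemokine gene Ccl2 was 7.4-fold higher and Cxcl2, a neutrophil attractant gene, 2.89-fold higher (4 arrays per group). Chemokines and immediate early genes were higher as groups, and genes of cholesterol synthesis and DNA replication were lower, in a test with a preset correlation between genes. None of these group results passed with an estimated correlation (lowest adjusted p = 0.458). Srebf2, the transcription factor gene that drives cholesterol synthesis genes, fell by 0.97 ± 0.07 on the log2 scale (SE, n = 4 per group), and the helicase subunit gene Mcm2 fell by 0.84 ± 0.06. Of 17444 genes, 3823 were higher and 6178 were lower with NM401 (limma, adjusted p below 0.05), and 1229 and 2654 of these differed by at least 1.5-fold. At least 4-fold differences were found for 30 higher and 249 lower genes. The 4 control and 4 NM401 values did not overlap in 53.2% of all genes, where chance gives 2.86%. The split between directions depended on the scaling, with 38.2% of calls higher in the values as scaled here, 49.5% after quantile normalisation (4776 higher, 4873 lower) and 64.5% after median scaling (6113 higher, 3360 lower). Each of these scalings sets a bulk measure of signal equal between arrays, so higher and lower are relative to the RNA signal of the same array. On that scale the spike-in probes stood 2.3 log2 units lower in NM401. Scaling to the spike-ins was not tried, but it would raise the log2 fold change of every gene by the same 2.3 units. Of the 6178 genes called lower, 249 were lower by at least 4-fold (2 log2 units). Most genes called lower here would thus be higher per amount of spike-in. Whether spike-in amounts were equal in both groups is not known. The median log2 fold change over all genes was -0.10 as scaled here, -0.01 after quantile normalisation and 0.11 after median scaling, and medians of gene lists are therefore also given relative to it. Fitted with slide as a block, 2216 genes were higher and 3525 lower, and within slide 1, where NM401 replicate 1 was set against the 4 control arrays, 752 were higher and 1362 lower. Both of these contrasts rest on NM401 replicate 1 alone, since slide 2 holds no control, and the fit within slide 1 takes its spread from the control arrays and assumes that the lone NM401 array varies like them.

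The largest increases with NM401 included the chemokine genes Ccl2 and Ccl7. Emp1, which encodes an epithelial membrane protein, showed the largest log2 fold change at 4.03 ± 0.45 (SE, limma adjusted p = 0.000234), and its probe lies on chromosome 4 at 172335071 to 172335130 of rn4. Emp1 was well above background on 2 of the 4 control arrays and on all 4 NM401 arrays. Ccl2, a chemokine that draws monocytes, was well above background on all arrays and rose by 2.89 ± 0.13 on the log2 scale (SE, limma adjusted p = 2.47e-05), and its probe lies on chromosome 10 at 70257919 to 70257978. The related chemokine Ccl7 rose by 2.70 ± 0.44 with 1 of 4 control arrays well above background, and the neuropeptide gene Nmb by 2.76 ± 0.13 with 2 of 4. Rgs1, a regulator of G-protein signalling, rose by 2.40 ± 0.25. For the increases that follow, the probe was not well above background on any control array, and the differences are bounds. Dusp1, a phosphatase that acts on MAP kinases, was at least 7.89-fold higher, Rsad2, an interferon-induced antiviral gene, at least 6.38-fold, Fos, a subunit of the AP-1 transcription factor, at least 5.95-fold, and Slc6a8, a creatine transporter, at least 5.52-fold higher. Gsg1 was at least 4.21-fold higher and Akap2, which anchors protein kinase A, at least 3.44-fold higher. These genes were all called with slide as a block, where their log2 fold changes lay between 2.18 and 4.27, whereas within slide 1 Ccl7 (limma adjusted p = 0.0873) and Akap2 (limma adjusted p = 0.0655) missed the threshold. With normexp background correction, log2 fold changes were far smaller for the dim genes, at 0.71 for Dusp1, 0.67 for Rsad2, 0.44 for Fos, 0.42 for Slc6a8, 0.33 for Gsg1 (not called) and -0.02 for Akap2 (not called), so the bounds depend on the background method, as do the values of Emp1 (2.42), Nmb (0.99) and Ccl7 (0.53), while Ccl2 stood at 2.81 or more in each alternative.

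Most of the largest decreases were in genes not well above background on every NM401 array. Emilin2, which encodes an extracellular matrix glycoprotein, was well above background on all 8 arrays and fell by 3.30 ± 0.22 on the log2 scale (SE, limma adjusted p = 4.55e-05), and its probe lies on chromosome 9 at 110458102 to 110458161. Ces2a, a carboxylesterase gene, was at least 7.40-fold lower and Hcrtr1, an orexin receptor gene, at least 4.80-fold lower, each with a probe not well above background on any NM401 array, although another probe of Ces2a, not tested, was so on 1 of them. Log2 fold changes were -3.47 ± 0.48 for Kptn, -3.45 ± 0.67 for Tcte1, -3.41 ± 0.48 for Cfi (complement factor I) and -3.37 ± 0.69 for Nnmt (nicotinamide N-methyltransferase), each well above background on 1 of 4 NM401 arrays. Brinp2 fell by 3.34 ± 0.33 and Gpr63 by 3.29 ± 0.53, with 2 of 4 NM401 arrays well above background. Alk, a receptor tyrosine kinase gene, fell by 3.20 ± 0.75, with 3 control arrays and 1 NM401 array well above background. Sdccag8 fell by 3.26 ± 0.59 at its brightest probe, while its 5 tested probes included called probes of opposite direction, and without any 1 control replicate another probe represented it at 0.09 to 0.19. With slide as a block, the log2 fold changes of these genes lay between -3.11 (Emilin2) and -1.40 (Nnmt), and Nnmt, Tcte1, Alk, Sdccag8 and Gpr63 missed the threshold (limma adjusted p = 0.151, 0.119, 0.222, 0.0811 and 0.0505). Within slide 1 alone, Emilin2, Brinp2 and Kptn of these genes were called (limma adjusted p = 0.0348, 0.0384 and 0.0414). With normexp, log2 fold changes lay at -2.83 for Emilin2, from -2.18 (Brinp2) to -1.53 (Hcrtr1) for the others and at -0.10, not called, for Sdccag8, and the values of Ces2a (-1.71) and Hcrtr1 (-1.53) were smaller than their bounds, as they were with slide as a block (-2.56 and -2.11).

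**Figure D2:**
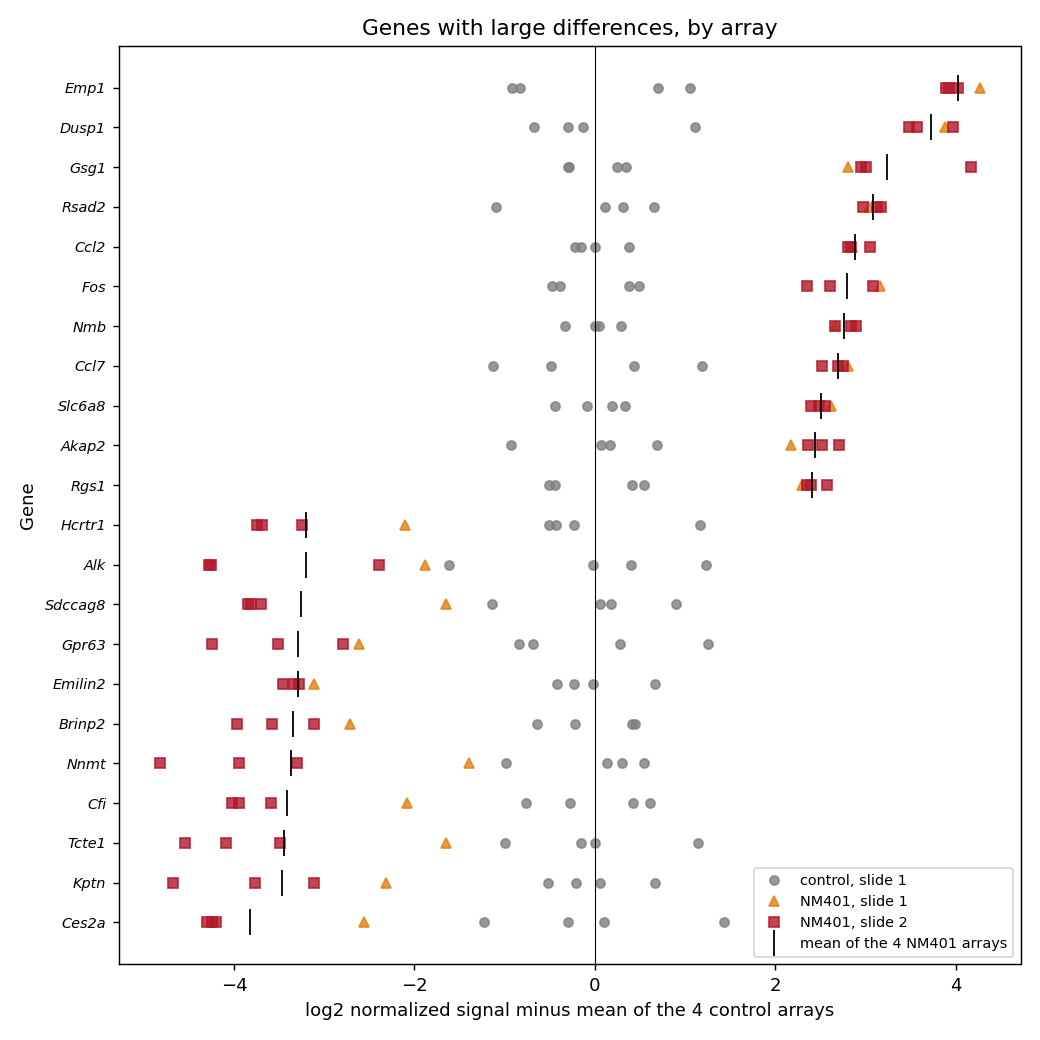
Log2 normalized signal of each array minus the mean of the 4 control arrays (horizontal axis) for the genes with large differences named in the text (vertical axis), with arrays marked by group and slide and the NM401 mean as a vertical tick, at fitted values also where the text gives a bound. NM401 replicate 1, on slide 1 with the controls, lies near the other NM401 arrays for the increases and between them and the controls for most decreases, as for Nnmt with -1.40 against a mean of -3.37 over the 4 NM401 arrays.

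Of the 26 lists tested, 3 were higher and 4 were lower with NM401 (camera, adjusted p below 0.05). With an estimated inter-gene correlation none of the 26 passed, 1 had an unadjusted p under 0.05, and the lowest adjusted p was 0.458, whereas fry, which does not compare a list with other genes, called 19. List results with slide as a block or within slide 1 rest on NM401 replicate 1 alone and on the preset correlation. Immediate early genes, which respond to stimuli without new protein synthesis, were higher as a list (camera adjusted p = 0.00382, and adjusted p = 0.458 with an estimated correlation). Of 22 measured members 13 rose, 3 fell and 6 did not pass, with the same counts adjusted over the list alone. Beside Dusp1 and Fos, the AP-1 subunit gene Junb rose by 0.80 ± 0.09 and the transcription factor gene Klf6 by 0.78 ± 0.06, while Junb stood at 0.37 with normexp and Klf6 at 0.28 as a mean of its probes. The members that fell were Egr3, Fosl2 and Ier5. The median of the list was 0.50, or 0.48 with dim members at their bounds, which is 0.60 above the median of all genes. It was called with slide as a block (camera adjusted p = 0.00246), and within slide 1 its median was 0.46 (camera adjusted p = 0.00399). Across the alternatives its adjusted p ranged from 4.39e-06 to 0.458.

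Chemokines were also higher as a list (camera adjusted p = 0.00845, and adjusted p = 0.458 with an estimated correlation). Of 16 measured members 10 rose (Ccl2, Ccl3, Ccl4, Ccl5, Ccl7, Ccl9, Ccl12, Ccl17, Cxcl1 and Cxcl2), 3 fell (Ccl22, Cxcl9 and Cxcl10) and 3 did not pass, with the same counts adjusted over the list alone. Cxcl2, a neutrophil attractant, rose by 1.53 ± 0.17. Cxcl1 was at least 2.75-fold and Ccl12 at least 1.86-fold higher, both with a probe not well above background on any control array. With normexp background correction Cxcl1 stood at -0.06 (not called) and Ccl12 at -0.25, where it was called lower (limma adjusted p = 0.0373). With the deposited series values they stood at 0.17 and -0.11 (neither called), so the direction of these dim genes turned with the background method. The list's median was 0.76, or 0.71 with bounds, which is 0.86 above the median of all genes. It was called with slide as a block (camera adjusted p = 0.00883), and within slide 1 its median was 0.70 (camera adjusted p = 0.0114), but it missed the threshold on probes well above background on all 8 arrays (camera adjusted p = 0.0746, over a range of 3.05e-05 to 0.458 across its alternatives).

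Mitosis genes were the third list that was higher (camera adjusted p = 0.0168, and adjusted p = 0.458 with an estimated correlation), while DNA replication genes were lower (camera adjusted p = 0.0127, and adjusted p = 0.458 with an estimated correlation). Of 24 mitosis genes 8 rose, 2 fell (Kif20a and Plk1) and 14 did not pass. The kinetochore gene Ndc80 rose by 0.87 ± 0.05 at its brightest probe and stood at -0.01 as a mean of its 3 probes, which differed in sign. The spindle checkpoint kinase gene Bub1 rose by 0.79 ± 0.06, Birc5 by 0.77 ± 0.10 and Cenpf by 0.65 ± 0.09. Of 29 DNA replication genes 18 fell, 0 rose and 11 did not pass. Mcm2 fell by 0.84 ± 0.06, Mcm6 by 0.77 ± 0.06 and Mcm5 by 0.49 ± 0.05, all subunits of the replicative helicase, and the DNA ligase gene Lig1 fell by 0.57 ± 0.05. Counts adjusted over each list alone were the same. The list medians were 0.11 for mitosis and -0.26 for DNA replication, or 0.21 and -0.17 relative to all genes. Both were called with slide as a block (camera adjusted p = 0.00246 and 0.0231), and within slide 1 their medians were 0.18 and -0.18 (camera adjusted p = 0.00369 and 0.0442). Mitosis missed the threshold without NM401 replicate 1 (camera adjusted p = 0.0527) and with the mean of all probes of a gene (0.0749), over a range of 2.04e-05 to 0.458. DNA replication missed it with normexp (camera adjusted p = 0.19), median scaling (0.0848), no filter on dim probes (0.0517) and the deposited series values (0.107), over a range of 8.12e-05 to 0.458.

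Genes of cholesterol biosynthesis and uptake were lower (camera adjusted p = 0.00845, and adjusted p = 0.458 with an estimated correlation). Of 24 measured members 14 fell, 1 rose (Fdft1) and 9 did not pass, with the same counts adjusted over the list alone. Tm7sf2, a sterol reductase gene, fell by 1.07 ± 0.06, and Srebf2, the transcription factor that drives cholesterol synthesis genes, by 0.97 ± 0.07. The synthesis enzyme genes Dhcr7 and Mvd fell by 0.78 ± 0.07 and 0.73 ± 0.05, and Sqle and Insig1 were among the other members that fell. The median was -0.29, or -0.19 relative to all genes. The list was called with slide as a block (camera adjusted p = 0.00416), and within slide 1 its median was -0.32 (camera adjusted p = 0.00835). It missed the threshold with normexp (camera adjusted p = 0.111) and the deposited series values (0.0744), over a range of 5.05e-05 to 0.458. Lipid efflux and LXR target genes were not called as a list (camera adjusted p = 0.734, with a direction that turned after quantile normalisation), with 4 of 15 members higher, 8 lower and 3 not called, among them the lipid-binding Fabp4 at 2.06 ± 0.14 and the apolipoprotein gene Apoe at 0.89 ± 0.10, the latter at 0.21 and not called with normexp.

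Cytosolic ribosomal proteins (camera adjusted p = 0.00382) and oxidative phosphorylation genes (camera adjusted p = 0.0261) were lower as lists, each with adjusted p = 0.509 with an estimated correlation. Of 30 ribosomal protein genes 22 fell, 2 rose and 6 did not pass, among them Rps18 with a fall of 0.83 ± 0.08, Rpl32 of 0.68 ± 0.07 and Rpl19 of 0.63 ± 0.07. After quantile normalisation Rps18 stood at -0.17, Rpl19 at -0.16 and Rpl32 at -0.03, the last not called. The match of 1 member to the array rests on a related name and is uncertain. After quantile normalisation the direction of this list turned, with 12 members higher and 7 lower, a median 0.11 above that of all genes against -0.17 as scaled here, and a camera adjusted p of 0.359. Of 26 oxidative phosphorylation genes 17 fell, 3 rose (Ndufa1, Ndufa2 and Ndufa4) and 6 did not pass. Cox5b fell by 0.79 ± 0.09, Cox5a by 0.59 ± 0.05, Atp5f1a by 0.54 ± 0.06 and Cox4i1 by 0.50 ± 0.05, while after quantile normalisation Cox5a stood at -0.29, Atp5f1a at -0.15 and Cox4i1 at 0.01. Oxidative phosphorylation was not called after quantile normalisation (camera adjusted p = 0.333), with normexp (0.628), median scaling (0.151), no filter on dim probes (0.102), the filter on all 8 arrays (0.0746), the deposited series values (0.443) or the replicate block (0.0533), without control replicate 3 (0.0636), or within slide 1 (0.131, median -0.30), over a range of 0.000371 to 0.628. Ribosomal proteins missed the threshold with normexp (camera adjusted p = 0.238) and the deposited series values (0.163), over a range of 0.000371 to 0.509. Both lists were called with slide as a block (camera adjusted p = 0.00124 and 0.0454), and within slide 1 the ribosomal protein median was -0.37 (camera adjusted p = 0.00292). Counts adjusted over each list alone were the same.

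**Figure D3:**
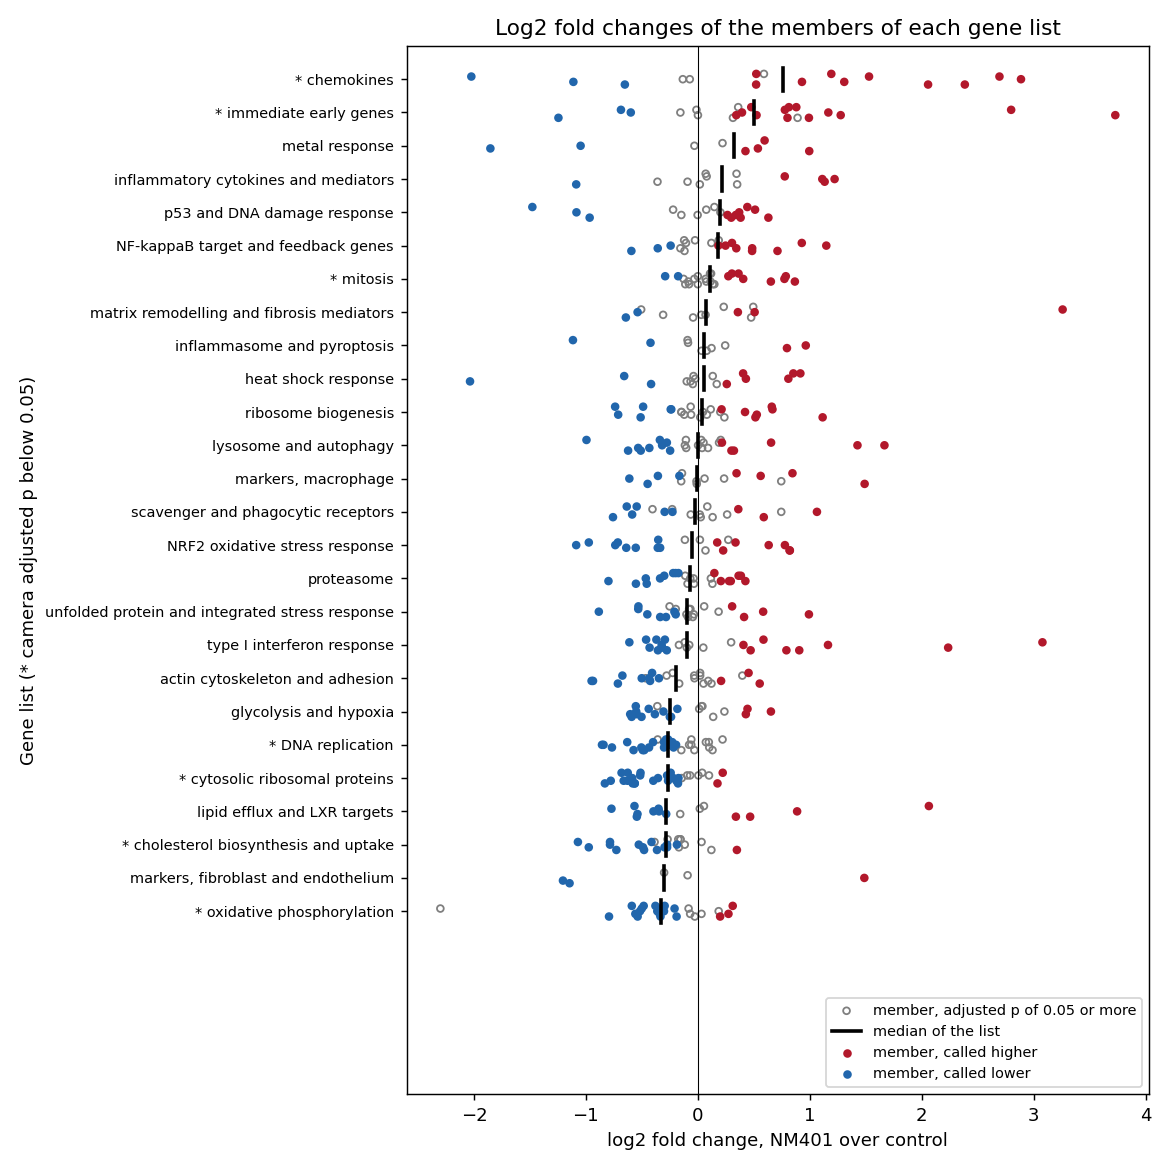
Log2 fold change, NM401 over control (horizontal axis), of the measured members of each of the 26 lists tested (vertical axis), with filled points for members called higher or lower, open points for the others, members dim in a group at their fitted value and not their bound, and a bar at the list's median. Medians run from -0.33 for oxidative phosphorylation to 0.76 for chemokines, and an asterisk marks the 7 lists with a camera adjusted p below 0.05.

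Other lists of inflammation and defence held members that moved both ways and were not called, and counts adjusted over the list alone were the same where no other count is given here and for the lists that follow. Among inflammatory cytokines and mediators (camera adjusted p = 0.143) 4 of 12 rose and 1 fell, or 3 and 1 adjusted over the list alone, with the interleukin gene Il1a at 1.22 ± 0.13 and Tnfsf9 at 1.13 ± 0.09, which with normexp stood at 0.25 and was not called. NF-kappaB target and feedback genes (camera adjusted p = 0.124) had 9 of 19 higher and 3 lower, including Zc3h12a, an RNase gene that limits cytokine messages, at 0.93 ± 0.09 and the survival gene Bcl2a1 at 0.71 ± 0.08. This list was called higher with normexp (camera adjusted p = 0.042) and with no filter on dim probes (0.00212). Of 10 inflammasome and pyroptosis genes 2 rose and 2 fell (camera adjusted p = 0.644), with Casp4 at 0.80 ± 0.09 and Txnip at -1.11 ± 0.08. Type I interferon genes split into 8 higher and 9 lower of 23 (camera adjusted p = 0.655), with Ifit3, well above background on 1 control array, at 2.24 ± 0.20 and Isg15 at 0.79 ± 0.07. Ifit3 stood at 0.46 with normexp. Of 13 matrix remodelling and fibrosis mediators 3 rose and 2 fell (camera adjusted p = 0.283), with Timp2 at -0.54 ± 0.08, or -0.20 after quantile normalisation.

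Stress lists were likewise mixed. The NRF2 oxidative stress list had 7 of 20 higher and 9 lower (camera adjusted p = 0.977), or 8 and 9 adjusted over the list alone, with the sulfiredoxin gene Srxn1 at 0.82 ± 0.05 and the thioredoxin gene Txn1 at -0.71 ± 0.06, the latter at -0.09 and not called after quantile normalisation. The metal response list had 4 of 8 higher and 2 lower (camera adjusted p = 0.283), or 5 and 2 adjusted over the list alone, and the 2 that fell were the metallothionein genes Mt1, by 1.85 ± 0.09, and Mt2A, by 1.05 ± 0.12. In the unfolded protein and integrated stress response list 4 of 22 rose and 8 fell (camera adjusted p = 0.734), with Atf4 at 0.58 ± 0.06 and Ddit4 at -0.88 ± 0.07. Of 16 heat shock genes 6 rose and 3 fell (camera adjusted p = 0.235), with the cochaperone genes Dnaja1 at 0.92 ± 0.05 and Chordc1 at 0.81 ± 0.07, and the list was called higher with normexp (camera adjusted p = 0.0409) and with no filter on dim probes (0.00549). The p53 and DNA damage list had 8 of 17 higher and 3 lower (camera adjusted p = 0.245), with the members of smallest p both lower, Tp53inp1 at -0.97 ± 0.06 and the pro-apoptotic Bbc3 at -1.08 ± 0.07.

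The remaining lists were not called. Glycolysis and hypoxia genes had 3 of 21 higher and 12 lower (camera adjusted p = 0.283), with Eno1 at -0.59 ± 0.06 and Gapdh at -0.55 ± 0.06, the latter at -0.08 and not called after quantile normalisation. Ribosome biogenesis had 7 of 24 higher and 6 lower (camera adjusted p = 0.373), with Rrs1 at 1.12 ± 0.09 and Nop56 at 0.67 ± 0.05. Of 23 proteasome genes 7 rose and 9 fell (camera adjusted p = 0.976), with Psmb5 at -0.80 ± 0.06 and Psmb4 at -0.55 ± 0.05. Scavenger and phagocytic receptors had 3 of 18 higher and 6 lower (camera adjusted p = 0.971), with Axl at -0.76 ± 0.08 and Scarb1 at -0.63 ± 0.05. Lysosome and autophagy genes had 6 of 25 higher and 9 lower (camera adjusted p = 0.971), with the proton pump subunit gene Atp6v0d2 at 1.67 ± 0.11 and the autophagy kinase gene Ulk1 at -0.99 ± 0.09. Actin cytoskeleton and adhesion genes had 3 of 24 higher and 9 lower (camera adjusted p = 0.45), with Actg1 at -0.95 ± 0.10 and Myh9 at -0.94 ± 0.09. Median and mean differed in sign for metal response (0.32 and -0.02), the p53 list (0.20 and -0.01), type I interferon (-0.10 and 0.27) and macrophage markers (-0.01 and 0.16). The camera direction, which is relative to all genes, was up for the NRF2, proteasome and scavenger receptor lists although their medians were -0.05, -0.07 and -0.02, and these medians were above 0 after quantile normalisation (0.08, 0.06 and 0.17). It was also up for type I interferon, whose median of -0.10 was still below 0 after quantile normalisation (-0.06).

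Of 15 measured macrophage markers 4 rose and 4 fell (camera adjusted p = 0.644), including the adaptor gene Tyrobp at 0.35 ± 0.05 at its brightest probe. That probe differed in sign from the other probe of Tyrobp, and the mean of both gave -0.33, called lower (limma adjusted p = 0.00147). Among markers of other cell types few were measured. Of 12 epithelial markers 1 was measured, Ager, at 0.99 ± 0.09, or 0.29 with normexp. Of the lymphocyte markers on the array 3 were measured, of which 2 fell, Nkg7 by 1.24 ± 0.08 and Cd3d by 0.79 ± 0.13. Of 8 neutrophil markers 3 were measured and all 3 fell, among them the myeloperoxidase gene Mpo, at least 4.76-fold lower with a probe not well above background on any NM401 array, and Camp by 0.49 ± 0.13. The log2 fold change of Mpo was -1.89 with slide as a block and -1.32 with normexp, both smaller than that bound. Of 10 fibroblast and endothelial markers 5 were measured (camera adjusted p = 0.694), with 1 higher and 2 lower, or 1 and 3 adjusted over the list alone, including Dcn at 1.49 ± 0.09 and Col1a2 at -1.20 ± 0.12. Camp and Cd3d missed the threshold with slide as a block (limma adjusted p = 0.351 and 0.0515), Camp also with median scaling, and of the genes given with values here only Camp had control and NM401 values that overlapped.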

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

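What the slide tests below should show was written after the results had been seen, although the fit with slide as a block had been fixed beforehand. The reading of the ribosomal protein value below was also chosen after the results had been seen. Of 242 groups of 4 values checked, 15 held 1 array far from the other 3, where chance gives about 1 in 20. In 9 of them the array was NM401 replicate 1, the NM401 array on slide 1. On the normalised log2 scale its values were 0.843 against 0.972 to 0.985 for Fabp4, 1.66 against 1.78 to 1.79 for Atp6v0d2, -0.899 against -0.933 to -0.928 for Cxcl2, -1.77 against -1.43 to -1.40 for Rrs1, 0.556 against 0.466 to 0.472 for Scarb1, 3.14 against 2.86 to 2.87 for Myh9, -6.78 against -8.52 to -8.31 for Mpo, -2.93 against -5.13 to -4.98 for Sdccag8 and -6.83 against -8.56 to -8.47 for Ces2a. The other arrays far from their group were NM401 replicate 4 for Gsg1 (-3.81 against -5.17 to -4.98), NM401 replicate 3 for Mcm6 (-0.222 against -0.357 to -0.335), NM401 replicate 2 for the mean of the oxidative phosphorylation list (2.96 against 3.29 to 3.34), control replicate 3 for Cox5b (5.61 against 5.28 to 5.33) and Col1a2 (-3.81 against -3.49 to -3.42), and control replicate 4 for Hcrtr1 (-3.78 against -5.45 to -5.17). The oxidative phosphorylation member Cycs had a log2 fold change of -2.30 (limma adjusted p = 0.401), with 3 of 4 NM401 arrays well above background. Whether that 1 member set the list's mean apart was not tested.

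The extent of the difference, with 57.3% of genes called, was weighed first. Of the 35 splits of the 8 arrays into 4 and 4, 1, the real one, gave as many genes in one direction (3823 higher and 6178 lower against 184 at most in the others). That share is the smallest that 35 splits allow and lies under 0.05, so chance assignment is unlikely for both counts. The splits cannot speak to row or the ratio of spike-in to RNA signal, which divide the arrays as the groups do. With slide as a block, 5426 genes, 54.3% of those called, were called in the same direction, and over these the median difference of NM401 replicate 1 from the control mean, in the direction called, was 0.60 on the log2 scale against 0.56 in NM401 replicates 2 to 4 (control SD 0.11), while over the other 4575 it was 0.29 against 0.41 (control SD 0.15). NM401 replicate 1 lay on the side called for 99.8% of all genes called. It was itself 1 of the 4 NM401 arrays that gave the calls, and its difference from the controls sets the contrast with slide as a block. The share and the medians of both parts were thus partly fixed by how the genes were chosen. These values also rest on 1 array, as slide 2 holds no control, so slide and exposure cannot be told apart for either part. Slopes of genes on the ratio of spike-in to RNA signal among the control arrays gave 28.3% of the median difference (23.8 to 35.5 without 1 control array). These slopes came from 4 control arrays with log2 ratios of 2.82 to 3.81 and were carried to NM401 ratios of 0.629 to 1.13. The NM401 ratios lie outside the range of the controls, so the slopes cannot decide how much of the difference the ratio gives. That ratio, row on the slide, handling and an effect of NM401 stay open.

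Chemokines and immediate early genes were weighed as the second pattern. With slide as a block the higher adjusted p of both lists in camera was 0.00883, but this contrast rests on NM401 replicate 1 and on the preset correlation (adjusted p = 0.458 with an estimated one, without the block), so slide and exposure cannot be told apart. The ratio of spike-in to RNA signal stays open, since slopes among the control arrays gave -2.41% of the median difference of the 23 members called higher, with a range of -99.3 to 64.1 without 1 control array. For the number of lists, 7 of the 35 splits gave as many as 3 in one direction and 4 gave as many as 4, with at most 5 in a split other than the real one, so chance is not excluded by this count for the 3 higher and 4 lower lists, although the 6 other splits with at least 3 lists all kept 3 control arrays together and so part of the real contrast, and 0 splits with 2 control arrays on each side gave as many. An effect of NM401 on these genes stays a hypothesis among the open explanations.

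Lower signal of ribosomal protein and oxidative phosphorylation genes was the third pattern. A bias between arrays that depends on signal is a candidate explanation: the medians of all genes in 5 bins of rising mean signal were -0.285, -0.07, -0.001, -0.019 and -0.182. Among 10000 random lists matched on mean signal, the oxidative phosphorylation median of -0.33 lay at percentile 10.4, within their central range of -0.383 to -0.068, so this bias stays open for that list. The ribosomal protein median of -0.269 lay at percentile 98.8, above the central range of -0.545 to -0.29, so neither outcome written beforehand (within the range, or below it) occurred. Genes of like signal had a lower median (-0.435), so this list did not fall more than genes of its signal. The random lists could themselves draw ribosomal protein genes. The bias cannot be told apart from an effect of NM401 here, and such an effect stays open for both lists.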

How the results depend on the processing

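The fit on slide 1 arrays alone was the one test here chosen after seeing the data. Of 1796 values of named genes under the alternatives, 1740 kept their direction and their side of the threshold, 45 kept the direction but missed the threshold and 11 turned. With the filter on all 8 arrays, 67 of the 91 genes were measured. The genes were chosen for large differences or small p, so these counts do not describe all genes called. Of 572 list results, 524 were the same, 27 lost and 16 gained a call and 5 turned. A list called in neither fit counted as the same even where its direction differed, as for NRF2 with slide as a block. Most lists were not called to begin with. The lists called kept their call and direction in 12 (oxidative phosphorylation) to 21 (immediate early genes) of 22 alternatives. Genes higher (3823) numbered 6113 with median scaling, 2216 with slide as a block, 752 on slide 1 arrays only and 1229 at a fold change of at least 1.5. Genes lower (6178) numbered 9403 with normexp, 3360 with median scaling, 3525 with slide as a block, 1362 on slide 1 arrays only and 2654 at a fold change of at least 1.5. The fewer arrays on slide 1 and the size threshold lower the counts by construction. With slide as a block the contrast rests on NM401 replicate 1 alone, which widens its error and also lowers the counts. Whether slide itself played a part, and the cause for the others, was not tested. Without 1 replicate, genes higher ranged from 3266 to 3712, genes lower from 5411 to 6146, lists higher from 2 to 3 and lists lower from 3 to 4. Oxidative phosphorylation missed the threshold without control replicate 3 (camera adjusted p = 0.0636) and mitosis without NM401 replicate 1 (camera adjusted p = 0.0527). Lists higher (3) numbered 5 with normexp, 9 with no filter on dim probes, 0 with an estimated correlation and 7 with fry. Lists lower (4) numbered 0 with normexp, 2 with quantile normalisation, 2 with median scaling, 2 with no filter on dim probes, 0 with the authors' series matrix values, 0 with an estimated correlation and 12 with fry.

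Cytosolic ribosomal proteins turned to higher, not called, with quantile normalisation (adjusted p = 0.359, over a range of 0.000371 to 0.509 across its alternatives). Calls were gained with no filter on dim probes by NF-kappaB target and feedback genes (0.00212), heat shock (0.00549), ribosome biogenesis (0.0192), matrix remodelling (0.0227), p53 (0.0301) and metal response (0.0498), and with normexp by heat shock (0.0409) and NF-kappaB genes (0.042), all higher. With fry, which tests a list against no change, 4 lists whose camera direction was up were called lower: NRF2 oxidative stress response (0.00333), proteasome (0.0131), scavenger and phagocytic receptors (0.0207), and lysosome and autophagy (0.000371). Log2 fold changes turned with normexp for Akap2 (-0.02), Cxcl1 (-0.06) and Ccl12 (-0.25, called lower), and with the authors' series matrix values for Ccl12 (-0.11), all dim in control. They turned with the mean of all probes for Ndc80 (-0.01) and Tyrobp (-0.33, called lower), whose tested probes differed in sign, and with quantile normalisation for Cox4i1 (0.01). Over the fits without 1 replicate Sdccag8 ranged from -3.79 to 0.19, and without 1 control replicate it stood at 0.09 to 0.19 (0.13, 0.19, 0.17 and 0.09), because another of its probes became the brightest. For the turns other than those of Ndc80, Tyrobp and Sdccag8 the cause was not tested.

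The replicate numbers did not pair the samples: deviations of same-numbered arrays from their group means correlated across genes at 0.19, -0.003, 0.08 and -0.07, and 3 of the 8 arrays correlated best with the array of their own number in the other group. With the replicate block, 3535 genes were higher and 5845 lower, 3 lists were higher and 3 lower, and oxidative phosphorylation alone lost its call (camera adjusted p = 0.0533). Signal over background limited the result for 102 genes called higher with a probe not well above background on any control array and 47 called lower with one not well above background on any NM401 array.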

Other observations

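The tests of families and the comparison of genes that differed by at least 4-fold were chosen after seeing the data. Genes were also grouped by the stem of their symbol, which gave 116 families with at least 10 measured members. With camera, 8 families were higher and 2 lower with NM401, and 0 passed with an estimated correlation, so the families are described only. The dual-specificity phosphatases (Dusp) had 9 of 17 members higher and 3 lower (camera adjusted p = 0.0393, and adjusted p = 0.576 with an estimated correlation), with a median 0.47 above that of all genes. Sorting nexins (Snx), which act in endosomal sorting, had 14 of 27 higher and 4 lower (camera adjusted p = 0.0287, and adjusted p = 0.433 with an estimated correlation). Centrosomal proteins (Cep) had 13 of 33 higher and 2 lower (camera adjusted p = 0.0104, and adjusted p = 0.576 with an estimated correlation), and the cochaperones named Dnajc 11 of 24 higher and 2 lower (camera adjusted p = 0.0287, and adjusted p = 0.576 with an estimated correlation). The other families higher were Ccdc, Trmt, Ccl and Zfp, and those lower were Rps and Rpl, whose medians lay above that of all genes after quantile normalisation (by 0.08 and 0.17). With slide as a block, a contrast that rests on NM401 replicate 1, Zfp lost its call (camera adjusted p = 0.118) and the other families kept theirs, with 0.0375 for Dusp, 0.0479 for Snx, 0.00467 for Cep and 0.0158 for Dnajc. For these 4 families the medians lay above that of all genes after quantile normalisation too. Keratins (Krt) had 0 of 10 members higher and 9 lower, but the family missed the threshold (camera adjusted p = 0.0639).

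Probes of the labelling spike-ins stood 2.3 log2 units lower in NM401 than in control relative to the 75th percentile of the same array, at 0.918 ± 0.21 (SD, n = 4) against 3.22 ± 0.48 (SD, n = 4; exact permutation p = 0.0286, the smallest possible), a ratio of 4.93-fold. NM401 replicate 1 on slide 1 stood at 0.629 and NM401 replicates 2, 3 and 4 at 1.13, 0.989 and 0.925, while the control arrays lay between 2.82 and 3.81. Of 10 spike-in probes, the 7 well above background on all arrays were used. Negative control probes lay at -8.11 ± 0.37 in control and -8.63 ± 0.23 in NM401 on the same scale (SD, n = 4).

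Among the 249 genes lower by at least 4-fold, 57.8% had a placeholder name, against 30% (9) of the 30 genes higher by at least 4-fold and 37.7% of all genes tested. NM401 replicate 1 had a median log2 difference from the control mean of -1.74 over these genes, and NM401 replicates 2 to 4 of -2.78. Over the 30 higher genes, the medians were 2.30 and 2.38.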
